A study of Mus musculus with 6 samples.

How the data were processed

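Total RNA from the apex of the heart ventricles of transgenic mice was extracted with Trizol, and 500 ng was amplified with the MessageAmp Premier kit, labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, per the labels. The labels define 2 groups, 3 PR-M expressing and 3 PR-M non-expressing samples. Replicates were numbered in the order of their records, so a number pairs no samples across groups.

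The values are the authors' deposited log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA (robust multi-array average, which corrects background, equalises array distributions and summarises probes) and Partek 6.6, with no role or order. The settings of the background correction, the summary and any filter are not given in the sources used here. The log2 scale was read from the values. The sorted values of the 6 arrays differed by at most 0.155, which fits quantile normalization between arrays. Such scaling removes any change that moves all genes together, so a difference here is relative to the other genes on the array. Probe intensities and scan data were not used here.

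The table holds 45101 probe sets, of which 64 are control probe sets that were left out of the tests and examined apart. The platform's annotation gives 1 gene symbol to 34945 of the 45037 tested probe sets, several to 932 and none to 9160. Symbols were set against the RefSeq gene table of the assembly GRCm38.p6 through the gene identifiers, and 0 changed. A probe set with several symbols or none was given no gene name. A probe set without a listed symbol is unnamed here and can still belong to a gene. Of genome positions only the chromosome of a gene, from the same table, was used.

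Expressing and non-expressing arrays were compared with the linear model of limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided). P-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The prior had 4.48 degrees of freedom beside 4 residual ones. All log2 differences are expressing minus non-expressing. SE is the moderated standard error. The first test ran over all 45037 probe sets. The second ran over 18193 genes, each represented by its probe set with the highest mean over the 6 arrays, and 9010 genes had more than 1 probe set. The third was camera with an inter-gene correlation of 0.01 over gene lists with at least 5 measured members. Camera with a correlation estimated from the residuals of each list and fry were run beside it, and statmod 1.5.0 was used for the random block. A total of 51 lists of pathways and cell type markers was written before the data were examined, and 50 had enough members. RNA quality measures were compared by exact permutation tests, two-sided, for which 10 splits of the 6 arrays give no p under 0.1.

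The rule for named genes was also set before the data were examined. It took probe sets past the threshold with 1 gene symbol and no overlap between groups, at most 12 in each direction by size of change. Where fewer than 5 passed in a direction it took the 10 with the lowest p, said not to pass. From each list described it took up to 4 members past the threshold over all genes, or the 2 with the lowest p as values. It added Pgr, Myh6 and sex-linked genes, of which Ddx3y was not analysed here. A gene outside the rule is said to be named after its values were seen.

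The fit over probe sets was tested on simulated data for this comparison, 3 simulations over 45037 probe sets with 200 probe sets changed in each. It called 16.9% of those changed by 0.5 on the log2 scale, 93.0% of those changed by 1 and 99.5% of those changed by 2, and 0.0171% of the unchanged ones. Changes well under 2-fold could therefore be missed with 3 arrays in each group. The simulated probe sets varied independently and held 200 true changes, so these shares need not hold for the real arrays. Larger changes could be missed too: over all probe sets Sln, with a log2 difference of 3.89, did not pass (limma adjusted p 0.0628).

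Alternatives fixed before the data were examined were a filter on dim probe sets, cyclic loess, quantile and median scaling, an intensity trend with a robust prior, array weights, the title prefix as a random block, leaving out probe sets ending in _x_at or _s_at, leaving out each array in turn, other thresholds, treat against a 1.2-fold change, ordinary statistics without the shared prior, the mean of all probe sets of a gene, and the other list tests. The title prefix was treated as a possible batch. Each prefix holds 1 group only, and the non-expressing group spans 2 prefixes, so it entered as a random block (duplicateCorrelation, consensus correlation 0.117). The block entered the fits over probe sets and genes but not the list tests. It allows for likeness of arrays within a prefix and cannot remove a prefix effect that follows the groups. The samples share no replicate numbers in the labels, so no paired fit was made.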

Results

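The series measured mRNA in the ventricular apex of the heart in mice carrying a human progesterone receptor of the mitochondrion, called PR-M. Total RNA of 6 samples was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, which carry several probe sets for many genes. The labels put 3 arrays in a PR-M expressing group and 3 in a PR-M non-expressing group. Progesterone, 2.5 mg in oil under the skin, was given for 19 to 21 days in both groups, so the comparison is between the PR-M groups under the hormone and not of the hormone itself. The labels do not say how PR-M expression was established, by genotype, promoter or measurement, so what parts the groups is known only by the group names. The labels do not say whether the arrays of a group came from separate animals, so the p-values measure the spread between these samples. The precision was limited by the number of arrays, 3 in each group.

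The deposited values are on a log2 scale and spanned 2.09 to 14.8, with array medians from 5.77 to 5.78. Pearson correlations between arrays over 45037 probe sets lay between 0.992 and 0.997. No pair of arrays was a duplicate. Non-expressing replicate 1 correlated least with its own group, with a mean r of 0.993 against 0.995 for each of replicates 2 and 3. The first principal component held 33.4% of the variance and placed the 3 expressing arrays at -24.3, -14.7 and -12.5 and the 3 non-expressing arrays at 31.3, 11.8 and 8.3. The sample titles of the expressing group share 1 prefix. Those of the non-expressing group have 2 prefixes, one for replicate 1 and one for replicates 2 and 3. The second principal component, with 26.7% of the variance, parted these 2 prefixes. It placed non-expressing replicate 1 at 24.7 and replicates 2 and 3 at -24.3 and -19.0, with the expressing arrays at 8.1, 0.8 and 9.7. No prefix held both groups, so values within a prefix could not be compared between groups.

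The 3 mouse Pgr probe sets, which read the endogenous progesterone receptor gene and say nothing of the human transgene unless it is similar in sequence, were dim in all 6 arrays. They lay between 3.14 and 4.70, and their differences were -0.14, -0.06 and -0.01, with adjusted p of 0.527, 0.861 and 0.988 in limma. Pgr therefore did not check the group labels. The brightest Myh6 probe set, for the main adult cardiac myosin heavy chain, was at 14.6 in both groups (SD 0.03 and 0.01, n = 3 each), close to the top of the scale, where a change would hardly show. The other Myh6 probe set was at 8.10 in the expressing and 8.87 in the non-expressing arrays, without overlap, and did not pass (log2 -0.77, SE 0.19, adjusted p 0.198). The Y-linked gene Eif2s3y was at 8.89 to 9.18 in all arrays, and the brightest Xist probe set was at 5.33 to 5.66 with a difference of 0.01. The brightest Kdm5d probe set lay between 7.16 and 7.73 and the brightest Uty probe set between 6.94 and 7.32 in all 6 arrays. No probe set of these sex-linked genes passed the test.

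Genes typical of atrial muscle were the largest rises in the expressing group. Sln, which encodes sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum, rose 14.8-fold, from 5.03 ± 0.12 to 8.92 ± 1.15 (SD, n = 3 each), with a log2 difference of 3.89 (SE 0.46). Its non-expressing level lay below the array medians of 5.77 to 5.78 and may be background, so the fold is uncertain. The atrial myosin light chain genes rose in the same arrays: Myl4 12.1-fold, with a log2 difference of 3.60 (SE 0.43), and Myl7 10.9-fold, with a log2 difference of 3.45 (SE 0.37). Nppb, which encodes brain natriuretic peptide, fell by 1.56 on the log2 scale (SE 0.19), a 2.95-fold difference. In all 4 genes the 3 expressing arrays did not overlap the 3 non-expressing arrays. The adjusted p was 0.0451 for Sln and Myl4, 0.0348 for Myl7 and 0.0453 for Nppb (limma, Benjamini-Hochberg over 18193 genes with 1 probe set each). These p lay close to the threshold: with the title prefix as a random block the 4 calls were lost, with an adjusted p of 0.0987 for Sln and Myl4, 0.0882 for Myl7 and 0.0990 for Nppb. They were also lost with an intensity trend and robust prior (adjusted p 0.132 for Sln, 0.136 for Myl4, 0.0897 for Myl7 and 0.0576 for Nppb), with treat against a 1.2-fold change (0.0606 for Myl7 to 0.141 for Nppb), with ordinary statistics (0.297 to 0.304) and with the mean of all probe sets of a gene (0.0873 for each). Without _x_at and _s_at probe sets Sln, Myl4 and Nppb were lost at an adjusted p of 0.0506. Left out in turn, expressing replicate 3 and non-expressing replicates 1 and 2 each ended all 4 calls, with an adjusted p for Sln of 0.120, 0.0730 and 0.191. Non-expressing replicate 3 ended those of Sln, Myl7 and Myl4, expressing replicate 1 those of Myl4 and Nppb, and expressing replicate 2 that of Nppb, while the log2 difference of Sln stayed between 3.23 and 4.28. A further, dim probe set of Sln differed by 0.14 and a further one of Myl4 by 0.02, and neither passed.

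In all, 12 of the 18193 genes passed, 6 higher and 6 lower. The other 3 rises were smaller. Abi3bp, which encodes a matrix protein, was 1.73-fold higher (log2 0.79, adjusted p 0.0451), Cenpb, a centromere protein gene, was 1.69-fold higher (log2 0.75, adjusted p 0.0453) and Fign, which encodes a microtubule-severing enzyme, was 1.65-fold higher (log2 0.72, adjusted p 0.0453). The other probe set of Cenpb, dim, differed by -0.33 and did not pass, and the mean of both Cenpb probe sets differed by 0.21 (adjusted p 0.350). The mean of all probe sets differed by 0.41 for Fign (adjusted p 0.219). The falls beside Nppb were Pabpn1, a nuclear poly(A)-binding protein gene (log2 -1.31, adjusted p 0.0083), Ampd2, an AMP deaminase gene (log2 -1.26, adjusted p 0.0048), Cnksr1, a scaffold protein gene of kinase signalling (log2 -0.91, adjusted p 0.0112), Eif4g2, a translation initiation factor gene (log2 -0.77, adjusted p 0.0134), and Gsdme, which encodes the pore-forming protein gasdermin E (log2 -0.64, adjusted p 0.0451). Gsdme was named only after its values were seen. With the mean of all probe sets of a gene the difference was -0.12 for Pabpn1 (adjusted p 0.547), -0.54 for Ampd2 (0.0873), -0.04 for Eif4g2 (0.847) and -0.34 for Gsdme (0.213), and these calls were lost. The calls of Abi3bp, Cenpb, Fign and Gsdme were lost whichever of the 6 arrays was left out, with an adjusted p from 0.0513 for Cenpb to 0.207 for Abi3bp and Gsdme, and with the title prefix as a random block. With 1 array left out the log2 difference of Cenpb stayed between 0.68 and 0.80 and that of Gsdme between -0.67 and -0.61. Without non-expressing replicate 2 the calls of Pabpn1 (adjusted p 0.0718), Ampd2 (0.0580), Cnksr1 (0.110) and Eif4g2 (0.110) were lost. Cnksr1 and Eif4g2 were also lost without expressing replicate 2 (0.0523 and 0.0611) or expressing replicate 3 (0.0509 and 0.0946), and Eif4g2 without non-expressing replicate 3 (0.0592). The count was small beside the 2076 genes (11.4%) at an unadjusted p under 0.05, of which 882 were higher and 1194 lower. It changed with each array left out. It was 0 without non-expressing replicate 2, 3 without expressing replicate 3 and 7 without expressing replicate 2 or non-expressing replicate 3. It was 10 without expressing replicate 1 and 18 without non-expressing replicate 1. Fewer arrays lower the power, which can by itself lower the count. Of the 12 genes, 6 were among the 10, 4 among the 18, 2 among the 3, 5 among the 7 without expressing replicate 2 and 4 among the 7 without non-expressing replicate 3. With the title prefix as a random block 4 genes passed, all of them falls, and with the mean of all probe sets of a gene 1 gene passed.

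**Figure D1:**
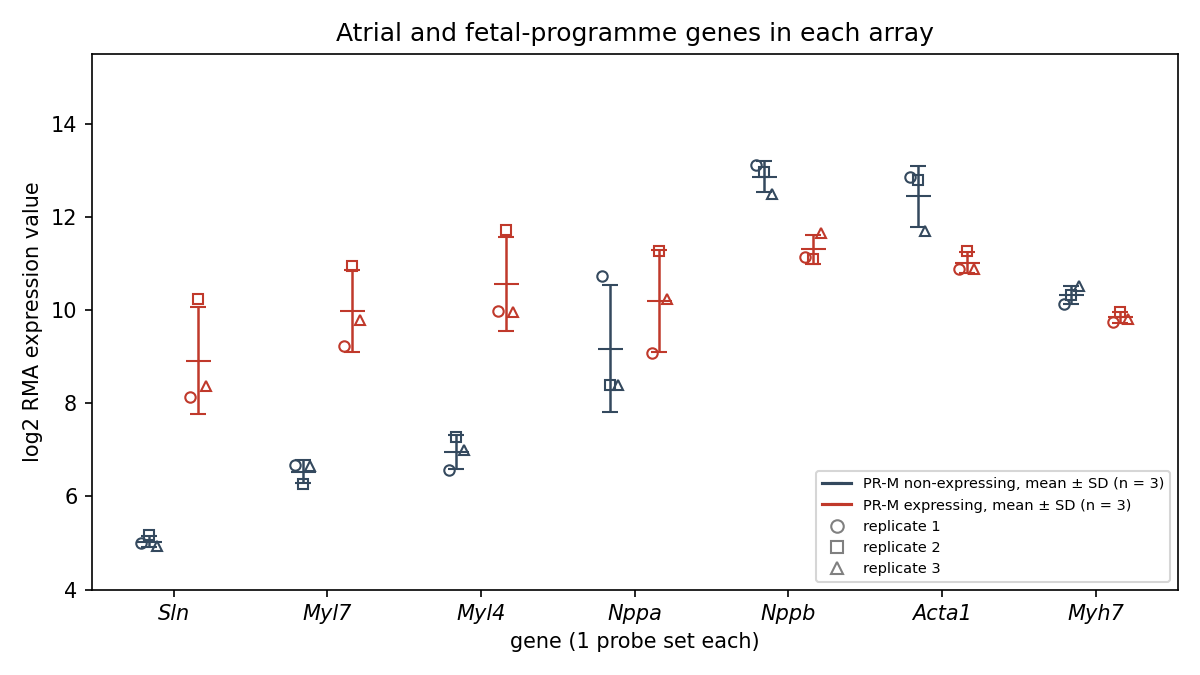
The log2 RMA expression value (vertical axis) of 7 genes (horizontal axis) in each array, with open symbols for replicates and bars for the group mean ± SD (n = 3). Sln, Myl7, Myl4 and Nppb parted the groups and passed the test, whereas Nppa overlapped and Acta1 and Myh7 did not pass.

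Tested probe set by probe set, 6 of 45037 passed, 5 of them lower in the expressing group. These 5 were probe sets of Aplp2, a homologue of the amyloid precursor protein gene (log2 -1.53, SE 0.12, adjusted p 0.0103), and of Pabpn1 (adjusted p 0.0103), Ampd2 (adjusted p 0.0103), Cnksr1 (adjusted p 0.0166) and Eif4g2 (adjusted p 0.0221). The 1 probe set that rose, 1451194_at, has no gene name in the platform table (log2 1.44, SE 0.11, adjusted p 0.0103), and it was named after its values were seen. Because fewer than 5 probe sets rose, the 10 named probe sets with the lowest p among those higher in the expressing group are given as values, and they did not pass. They belonged to Myl7, Slc24a2, Zfp462, Rsrc2, Abi3bp, Sln, Myl4, Cenpb, Fign and Trpm7, and their adjusted p lay between 0.0554 and 0.0639. Of those not given above, the probe set of Slc24a2 differed by 1.12, that of Zfp462 by 1.13, that of Rsrc2 by 0.91 and that of Trpm7 by 1.10. In the test over genes other, brighter probe sets stood for these genes. Their adjusted p was 0.684 for Slc24a2, 0.0648 for Zfp462, 0.328 for Rsrc2 and 0.686 for Trpm7. At an unadjusted p under 0.05 there were 5507 probe sets (12.2%). The 2 groups did not overlap in 18.6% of probe sets, where chance gives 10% on average for 3 against 3. Probe sets vary together, so a single split can lie far from 10%, and the share in other splits was not counted. No probe set passed without expressing replicate 3, or without non-expressing replicate 2 or 3, and 44 passed without non-expressing replicate 1, 13 without expressing replicate 2 and 11 without expressing replicate 1. With the title prefix as a random block 5 passed, and the Eif4g2 probe set was lost (adjusted p 0.0502).

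The falling probe sets of Aplp2, Pabpn1, Ampd2 and Eif4g2 did not speak for their genes as a whole. These 4 genes have 12 other probe sets, of which 11 were higher and 1 was lower in the expressing group, and none passed. Their median difference was 0.22, from -0.07 for Eif4g2 to 0.48 for Aplp2. The brightest Aplp2 probe set, which stands for the gene in the test over genes, differed by 0.48 (adjusted p 0.132) against -1.53 for the one that fell. Cnksr1 has a single probe set. With probe sets ending in _x_at or _s_at left out, Ampd2 and Eif4g2 were represented by other probe sets and the differences were 0.17 and 0.22, with adjusted p of 0.511 and 0.361.

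**Figure D2:**
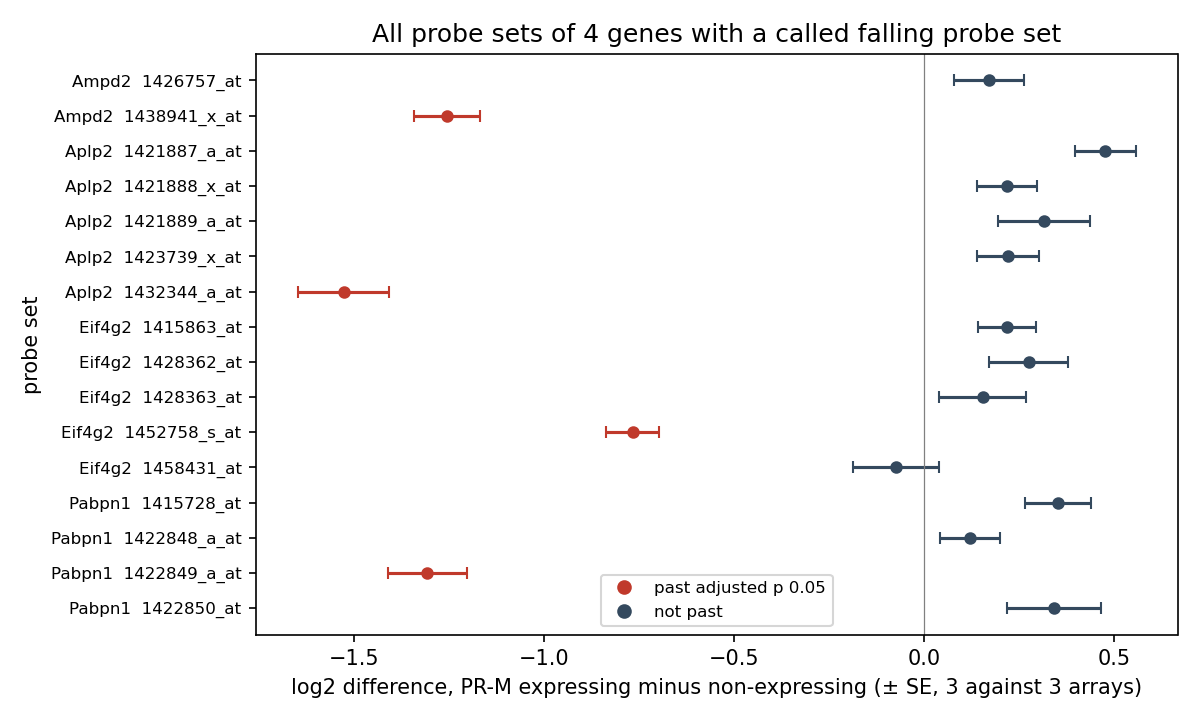
The log2 difference, expressing minus non-expressing (horizontal axis, ± SE, 3 against 3 arrays), of every probe set (vertical axis) of Ampd2, Aplp2, Eif4g2 and Pabpn1. In each gene 1 probe set fell past adjusted p 0.05, and 11 of the 12 others lay above 0.

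The control probe sets of 18S ribosomal RNA moved with the groups as well. They were lower in the expressing arrays, with a mean of 8.31 ± 0.22 against 9.88 ± 0.38 (SD, n = 3 each), without overlap (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays can give). The 3′ minus 5′ value of beta-actin, a measure of RNA integrity and labelling, was 1.23 ± 0.05 in the expressing and 1.38 ± 0.07 in the non-expressing arrays, without overlap (exact permutation p = 0.1, two-sided). That of Gapdh was 0.17 ± 0.06 and 0.25 ± 0.07 and overlapped (exact permutation p = 0.3, two-sided). That of 18S ribosomal RNA ran the other way, at 1.65 ± 0.30 and 0.85 ± 0.16 without overlap (exact permutation p = 0.1, two-sided). The hybridisation spikes differed by -0.15 (exact permutation p = 0.2) and the poly(A) spikes by 0.08 (exact permutation p = 0.6), both two-sided. These differences run alongside each gene and gene list described here.

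Among the 14 measured genes of the hypertrophy and fetal gene programme, Myl4 and Myl7 rose, Nppb fell and 11 did not pass over all genes. Adjusted over the list alone, 2 rose and 4 fell. Of those that did not pass over all genes, and named after their values were seen, Acta1, the skeletal actin gene that is active in the fetal heart, had a difference of -1.43 (SE 0.28, adjusted p 0.167), Ankrd23 one of -0.46 (adjusted p 0.141) and Nppa, the atrial natriuretic peptide gene, one of 1.02 (SE 0.70, adjusted p 0.603). Nppa was at 10.7 in non-expressing replicate 1 and at 8.39 in replicates 2 and 3. Myh7, the slow myosin heavy chain gene, was named as a member of the sarcomere list and differed by -0.48 (adjusted p 0.212). As a list the programme was not called by camera (adjusted p 0.525), with a median of -0.14, a mean of 0.25 and a direction in camera of lower. None of the 21 sarcomere genes passed over all genes and 1 fell adjusted over the list alone, with values of -0.48 for Myh7 and -0.27 for Mypn (list median 0.00, camera adjusted p 0.731). Of 17 calcium handling genes Sln rose and 16 did not pass, and the list was not called (median -0.01, mean 0.27, camera direction higher, adjusted p 0.239).

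Of 50 gene lists with at least 5 measured members, 8 passed in camera with the inter-gene correlation preset to 0.01, 7 higher and 1 lower in the expressing group. None of the 8 held with an estimated correlation, where the lowest adjusted p of all lists was 0.703 and 2 lists were under an unadjusted p of 0.05. That version of camera also uses only the 4 residual degrees of freedom, which raises p. The estimated correlation was -0.017 for the conduction list and 0.021 for complement, near or below the preset value. Their unadjusted camera p still rose from 6.58e-05 to 0.0141 and from 5.17e-04 to 0.0300, so correlation alone does not account for the loss. No list passed in the directional test of fry, whose lowest adjusted p was 0.217, with 5 lists under an unadjusted p of 0.05. In fry's mixed test, which asks whether the genes of a list change in either direction, 11 lists passed, among them sarcomere, proteasome and the hypertrophy programme, each at an adjusted p of 0.0048. The others were ion channels (0.0095), calcium handling (0.0114), uncoupling and antioxidants (0.0137) and conduction (0.0137). The atrial, adrenergic and Schwann lists (0.0163 each) and the steroid receptors (0.0317) passed too. The shifts were small beside the single genes above, with medians from -0.19 to 0.24 on the log2 scale.

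The lists of the tricarboxylic acid cycle and of fatty acid beta-oxidation were called slightly higher in the expressing group. All 17 measured genes of the tricarboxylic acid cycle had positive differences, with a median of 0.17. None passed over all genes and 1 rose adjusted over the list alone. The camera adjusted p was 1.20e-06 with the preset value, and the adjusted p was 0.813 with an estimated correlation. Ogdh, of the oxoglutarate dehydrogenase complex, differed by 0.34 (SE 0.08, adjusted p 0.213) and Sdhc, of succinate dehydrogenase, by 0.26 (SE 0.08, adjusted p 0.348). Of 20 genes of fatty acid beta-oxidation 19 were higher and 1 was lower, with a median of 0.10, and none passed over all genes or adjusted over the list alone. The median was 0.06 without expressing replicate 1 and 0.15 without non-expressing replicate 1. This list had a camera adjusted p of 6.53e-04, and its adjusted p was 0.813 with an estimated correlation. The thiolase gene Acaa2 differed by 0.31 (adjusted p 0.352) and Acadvl, the very long chain acyl-CoA dehydrogenase gene, by 0.23 (adjusted p 0.382).

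Other lists of fuel use and mitochondria were not called by camera, and no member of them passed over all genes. Of 21 genes of glycolysis and glucose oxidation 17 were higher and 4 lower (median 0.06, adjusted p 0.0615), with Pdhb at 0.29 and Pfkm at 0.17. Of 17 genes of ketone and branched-chain amino acid oxidation 12 were higher and 5 lower (median 0.06, adjusted p 0.217), with Ppm1k at 0.25 and Bckdhb at 0.19. The median was 0.02 for respiratory complex I (34 genes, adjusted p 0.0766), 0.02 for complexes III and IV (22 genes, adjusted p 0.0615), 0.03 for ATP synthase (16 genes, adjusted p 0.284), -0.02 for the mitochondrial ribosome (34 genes, adjusted p 0.783) and 0.03 for mitochondrial biogenesis and mtDNA (18 genes, adjusted p 0.217). The examples were Ndufv1 with 0.19 and Ndufs1 with 0.19, Cox7c with 0.56 and Uqcrc1 with 0.21, Atp5a1 with 0.10 and Atp5g2 with -0.11, Mrpl4 with 0.19 and Mrps14 with -0.18, and Tfam with 0.29 and Sirt3 with 0.31. The Cox7c probe set was far dimmer, at 6.85 in expressing and 6.29 in non-expressing arrays, than that of Uqcrc1, at 13.56 and 13.35. Adjusted over the list alone 1 gene of complexes III and IV rose. The 13 targets of PPAR alpha, a nuclear receptor that drives fat oxidation, had a median of 0.02 and a mean of -0.04 (adjusted p 0.943), with Ehhadh at 0.24 and Acot2 at -0.18.

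Lists bearing on the steroid itself were not called by camera, and no member passed over all genes. The 17 measured targets of the progesterone and glucocorticoid receptors had a median of 0.02 (adjusted p 0.769), with Hif3a at -0.13 and Tsc22d3 at 0.19. The 16 steroid receptors and cofactors had a median of 0.04 (adjusted p 0.176), with Stard3 at 0.70 (adjusted p 0.273) and Pgrmc1 at 0.24 (adjusted p 0.321), and they were among the 11 lists that passed in fry's mixed test (adjusted p 0.0317).

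The other lists called higher were the atrial, conduction, extracellular matrix, fibroblast and complement lists. The list of 11 atrial markers (camera adjusted p 0.0090, adjusted p 0.813 with an estimated correlation) held the 3 risen genes Sln, Myl4 and Myl7, while 8 did not pass. Adjusted over the list alone 4 rose. Its median was 0.10, and the call was lost without non-expressing replicate 1, with a median of -0.05 and an adjusted p of 0.0737. The median rested on single arrays: it was -0.02 without expressing replicate 2, 0.29 without expressing replicate 3, 0.22 without non-expressing replicate 2 and 0.30 without non-expressing replicate 3, while camera's direction stayed higher. It was 0.47 with dim probe sets left out. Of 10 conduction system markers 8 were higher and 2 lower, with a median of 0.24 (camera adjusted p 0.0011, adjusted p 0.703 with an estimated correlation). This median ranged from 0.15 with the mean of all probe sets of a gene to 0.33 without non-expressing replicate 3. None passed over all genes and 4 rose adjusted over the list alone. Tbx3 and Shox2, transcription factor genes of the pacemaker tissue, differed by 0.44 (SE 0.10, adjusted p 0.208) and 0.61 (SE 0.15, adjusted p 0.228).

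Of 31 genes of extracellular matrix and fibrosis 26 were higher and 5 lower, with a median of 0.12 (camera adjusted p 0.0015, adjusted p 0.813 with an estimated correlation). None passed over all genes and 1 rose adjusted over the list alone. Fn1, the fibronectin gene, differed by 0.60 (adjusted p 0.201) and Postn, the periostin gene, by 0.67 (adjusted p 0.256). The call was lost without expressing replicate 3, where the median was 0.01 and the adjusted p 0.135. Of 14 fibroblast markers, which share Col1a1, Col1a2, Dcn and Lum with the matrix list, 10 were higher and 4 lower, with a median of 0.15 (camera adjusted p 0.0185, adjusted p 0.813 with an estimated correlation). None passed over all genes or over the list alone, with Pdgfra at 0.22 and Dpt at 0.33. The call was lost without expressing replicate 2, expressing replicate 3 or non-expressing replicate 1, with medians of 0.07, 0.07 and 0.06 and an adjusted p of 0.0890, 0.135 and 0.124. It was also lost with cyclic loess (adjusted p 0.0735), with quantile renormalization (0.0526) and with dim probe sets left out (0.0751). All 12 complement genes were higher, with a median of 0.14 (camera adjusted p 0.0052, adjusted p 0.749 with an estimated correlation), and none passed over all genes or over the list alone. C1ra differed by 0.22 and C1s1 by 0.26. The median of the list was 0.09 without expressing replicate 1 or without non-expressing replicate 2.

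Interferon-stimulated genes were the list called lower. Of 25 measured members 22 were lower and 3 higher, with a median of -0.19 (camera adjusted p 0.0062, adjusted p 0.813 with an estimated correlation). None passed over all genes and 1 fell adjusted over the list alone. Rsad2, the viperin gene, differed by -0.56 (SE 0.11, adjusted p 0.156) and B2m, a subunit gene of the class I antigen complex, by -0.31 (SE 0.10, adjusted p 0.352). The call was lost without expressing replicate 3, with an adjusted p of 0.129, and without non-expressing replicate 2, with a median of -0.07 and an adjusted p of 0.467.

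**Figure D3:**
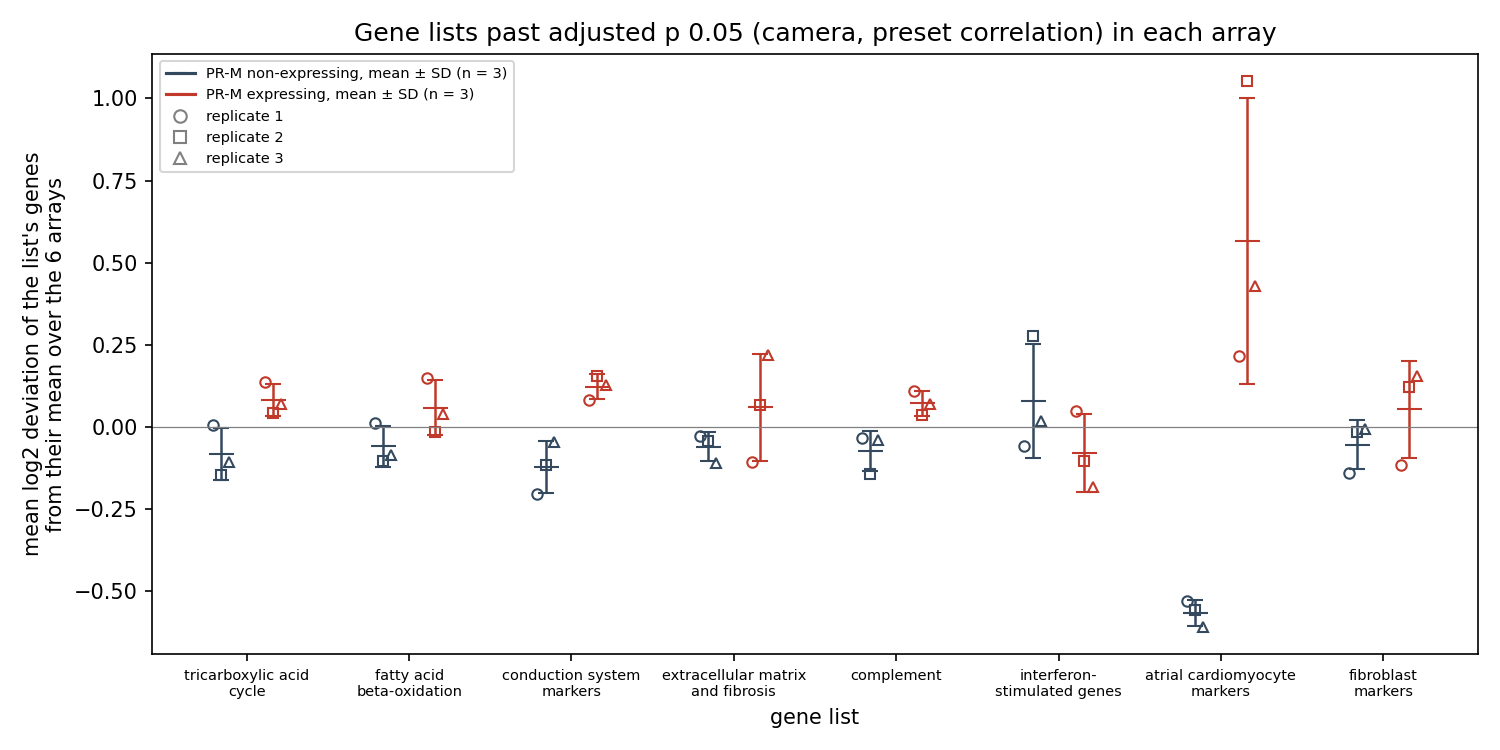
The mean log2 deviation of each list's genes from their mean over the 6 arrays (vertical axis) for the 8 lists past adjusted p 0.05 in camera with a preset correlation (horizontal axis), per array and as group mean ± SD (n = 3). The group ranges did not overlap for the tricarboxylic acid cycle, conduction, complement and atrial lists and overlapped for the other 4.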

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

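All tests in this part were chosen after the results they bear on had been seen.

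The control probe sets of 18S ribosomal RNA, which lie outside the main measurement, differed between the groups, by -1.08 for the 3′, -1.88 for the 5′ and -1.75 for the middle probe set, and these were the 3 of 64 control probe sets past adjusted p 0.05 in limma over the controls. A candidate explanation is RNA more degraded in one group. The 3′ minus 5′ value of beta-actin differed by -0.16 without overlap and that of Gapdh by -0.08 with overlap. With 3 against 3 arrays these values leave the explanation open. That of 18S ribosomal RNA itself differed the other way, by 0.80 without overlap. It comes from the same probe sets whose difference is to be explained, so it is no separate evidence. A batch that follows the title prefix cannot be told apart from the group here, because no prefix holds both, and a biological difference in ribosomal RNA was not tested.

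The rise of Sln, Myl7 and Myl4 was not the work of 1 expressing array. The smallest gap between the lowest expressing and the highest non-expressing array was 2.54, in Myl7, against an SD of at most 0.36 among the non-expressing arrays. These genes were chosen because they passed, so the gap describes them and is no separate test. Atrial tissue in the expressing samples is a candidate explanation that stays open. Expressing replicate 2 was the highest array in Sln, Myl7 and Myl4 alike. Sln was at 10.238 there against 8.138 and 8.380 in the other expressing arrays. Myl4 was at 11.723 against 9.985 and 9.959, and Myl7 at 10.955 against 9.220 and 9.786. This shared order goes with the explanation but does not single it out. Of 10 conduction system markers 8 were higher and 2 lower, with Tbx3 at 0.44 and Shox2 at 0.61. None of them passed over all genes. Nppa, abundant in atria, differed by 1.02 (95% interval -0.57 to 2.61), but its level in non-expressing arrays was too high and too variable to show a small share of atrial cells. Of the 8 other atrial markers 1, Dkk3, was above all non-expressing arrays in every expressing array, their median was -0.06, and Bmp10 differed by -0.03 at a mean level of 5.67, while a change of the ventricular muscle with PR-M was not tested apart from this.

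The probe sets of Aplp2, Pabpn1, Ampd2 and Eif4g2 fell while others of the same genes did not. A fall of the whole gene is argued against by the 12 other probe sets, whose median was 0.22, and 1 chromosome segment carried with the transgene is argued against because the genes lie on 4 chromosomes in GRCm38.p6. A signal that follows 18S ribosomal RNA predicts the slope between groups again within groups, a share of 1. The share was 0.06 (95% interval -0.17 to 0.29) for Eif4g2 and 0.04 (-0.62 to 0.70) for Ampd2, which argues against a full share of 1 for both. A part of the fall, up to a share of 0.70 for Ampd2, is not excluded. For Aplp2 the share was 0.48 (-0.09 to 1.06) and for Pabpn1 0.03 (-0.94 to 1.01), and these intervals include 1 and leave the explanation open. These slopes rest on 6 arrays. They bear on the fall only if 18S varies within groups for the reason it differs between them. A change of transcript form with PR-M, a sequence variant under the probes and a batch that follows the title prefix also stay open and were not tested.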

How the results depend on the processing

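The tests of other splits were chosen after the counts had been seen, and the alternatives before the data were examined. Under the 3 scalings the 6 probe sets and the 12 genes were the same, and no scaling moved the median of all probe sets by over 0.1. The deposited arrays already had nearly equal distributions, with sorted values at most 0.155 apart. Further scaling could change little, so this sameness says little about the normalization. Cyclic loess and quantile scaling each left 7 of the 8 lists, without the fibroblast list (adjusted p 0.0735 and 0.0526). The probe set count of 6 became 31 with dim probe sets left out, 37 with a trend and robust prior, 43 with array weights, 5 with the title prefix as a random block, 53 at adjusted p under 0.10, 318 at an unadjusted p under 0.05 with a 1.5-fold change and 2 with ordinary statistics. Without 1 array it ranged from 0 (without expressing replicate 3, non-expressing replicate 2 or non-expressing replicate 3) to 44 (without non-expressing replicate 1). The gene count of 12 became 23 with a trend and robust prior (8 of the 12 among them, without Sln, Myl4, Myl7 and Nppb), 26 with array weights, 4 with the title prefix as a random block, 3 without _x_at and _s_at probe sets, 27 at adjusted p under 0.10, 105 at an unadjusted p under 0.05 with a 1.5-fold change, 2 with treat, 1 with ordinary statistics and 1 with the mean of all probe sets. Without 1 array it ranged from 0 (without non-expressing replicate 2) to 18 (without non-expressing replicate 1). The list count of 8 became 13 with array weights, 0 with an estimated correlation and 0 with fry, and ranged from 7 to 14 without 1 array, the latter without non-expressing replicate 1. Camera did not take the random block. The block cannot part a prefix effect from the group, because no prefix holds both groups. No call here, of probe sets, genes or lists, was therefore tested against a batch that follows the title prefix. Looser thresholds and fewer tests act by construction. Fewer arrays lower the power, so they do not account for the rises to 44 probe sets and 18 genes without non-expressing replicate 1. The same holds for the 13 and 11 probe sets without expressing replicates 2 and 1. Non-expressing replicate 1 had the lowest array weight, 0.431. For these rises and for the other settings the cause was not tested. With _x_at and _s_at probe sets left out, Eif4g2 was at 0.22 and Ampd2 at 0.17, because other probe sets then stood for these genes. No other called gene changed sign, and no called list changed its direction in camera or fry. The median of the atrial list changed sign, from 0.10 to -0.04 with array weights, -0.02 without expressing replicate 2 and -0.05 without non-expressing replicate 1, and it was 0.47 with dim probe sets left out. Sln ranged from 2.01 to 4.28, Myl7 from 2.97 to 3.84, Myl4 from 1.81 to 3.90 and Nppb from -1.75 to -1.43, with adjusted p up to 0.304, 0.297, 0.304 and 0.304. Among the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave 6 or more probe sets and only 1, the real one, gave 12 or more genes, where the highest other count was 0 for each. For lists 7 of the 10 splits gave as many as the real 8, and the highest other count was 18, with expressing replicates 1 and 3 set with non-expressing replicate 1. The preset correlation was 0.01, and the median of the estimated ones was 0.153. Camera with estimated correlations also uses only the 4 residual degrees of freedom, so the correlation is not the only difference between the 2 versions. With 10 splits no share can fall under 0.05. No detection calls were used, so which dim probe sets lie at background is not known.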

Other observations

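Lists of other tissues and of stress were not called by camera in limma, and their values are given with the adjusted p. For markers of other cell types the median was 0.03 for endothelial cells (15 genes, 0.217), 0.08 for macrophages and monocytes (15 genes, 0.239), -0.08 for lymphocytes (15 genes, 0.239), 0.04 for smooth muscle and pericytes (14 genes, 0.676), 0.09 for adipocytes (10 genes, 0.284), 0.05 for Schwann and neuronal cells (11 genes, 0.264), 0.04 for the epicardium and mesothelium (10 genes, 0.765), -0.11 for skeletal muscle (16 genes, 0.0766) and -0.02 for red blood cells (7 genes, 0.743). No member passed over all genes. Adjusted over the list alone 1 Schwann and neuronal marker rose and 1 epicardial and mesothelial marker fell. The members with the lowest p were these: Mbp, the myelin basic protein gene, differed by 0.88 (SE 0.14, adjusted p 0.117), Vwf by 0.73 (adjusted p 0.333) and Tbx18 by -0.47 (adjusted p 0.236).

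Immediate early genes had a median of -0.08 (22 genes, adjusted p 0.176), with 1 fall adjusted over the list alone, and Ccn1 differed by -0.79 (SE 0.18, adjusted p 0.208) and Myc by -0.37. The integrated stress response under ATF4 had a median of -0.07 (22 genes, adjusted p 0.264), with Trib3 at -0.31 and Psph at -0.27. The heat shock response had a median of -0.04 and a mean of 0.02 (13 genes, adjusted p 0.677), with Hspb7 at -0.24 and Dnajb1 at 0.60. Ion channels and gap junctions had a median of 0.09 (17 genes, adjusted p 0.176), with Kcnh2 at 0.47 (adjusted p 0.184) and Kcnd3 at 0.27. Adjusted over the list alone 1 of them rose. Adrenergic and natriuretic signalling had a median of 0.04 (14 genes, adjusted p 0.135), with Pde4d at 0.35 (adjusted p 0.214) and Adra1b at 0.34. Here too 1 gene rose adjusted over the list alone. Of 17 genes of uncoupling, mitochondrial carriers and antioxidants 9 were higher and 8 lower (median 0.02, adjusted p 0.882), with Nqo1 at -0.50 (SE 0.08, adjusted p 0.132) and Prdx3 at 0.27. In this list 1 gene fell adjusted over the list alone.

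These counts were chosen after the values were seen. At an unadjusted p under 0.001, 196 probe sets were higher in the expressing group and 89 lower. Of the higher ones 35.7% had no gene symbol, and of the lower ones 10.1%, against 20.3% of all tested probe sets.

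The 12 called genes lie on 9 chromosomes in GRCm38.p6, with at most 2 on any of them.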
